A study of Homo sapiens with 14 samples.

How the data were processed

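RNA of THP-1 cells, an established human line grown from an acute monocytic leukaemia, was measured on 14 Affymetrix 1-colour arrays. Cells had been kept for 24 hours at 32 °C or at 37 °C, and the arrays form 7 pairs, each with 1 culture at either temperature. A pair shares its culture session in the labels. The sessions fall into 3 calendar periods, called A, B and C here, with 2, 2 and 3 pairs.

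The deposited table holds 1 intensity per probe set and array on a linear scale, from 0.01 to 15218.4. Per the labels, the material was labelled by an Affymetrix protocol and stained with phycoerythrin. The algorithm that turned probe values into these intensities, its version and its scaling target are not given in the sources used here. In every deposited column the mean left after trimming 2% of the values at either end lay between 99.9765 and 99.9783, so the intensities had been scaled to 1 common level, and an intensity is relative to its array's total. A shift shared by most transcripts would be removed by such scaling. Detection calls were not used here. The number of arrays limits the precision, since intensities carry no count of molecules.

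The table holds 22283 probe sets. Of these, 68 are Affymetrix control probe sets and were left out of the tests. In the platform annotation, 19065 of the other probe sets carry 1 gene symbol, 1043 carry several and 2107 are not listed with a symbol. Genes were named only from probe sets with 1 symbol, which cover 11963 genes. Symbols were compared with a RefSeq gene table through their Entrez identifiers. No symbol needed an update, and the identifiers of 12 probe sets were not in that table. Genes whose only probe sets carry several symbols, among them some heat shock genes, were not analysed here. No genomic coordinates are printed, because the files name no genome build.

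Intensities were transformed as log2(intensity + 7.3), where 7.3 is the 20th percentile of the whole table. This pseudocount makes fold changes of dim probe sets smaller than their ratios of intensity. Column medians spanned 0.21 on the log2 scale, under the limit of 0.5 set beforehand, so the arrays were used as deposited. Probe sets with a mean under the 40th percentile were left out, which left 13329. A linear model with the pair as a block was fitted in R 4.3.3 with limma 3.58.1, using lmFit and eBayes with an intensity trend. All differences are 32 °C minus 37 °C. P-values were adjusted by the Benjamini-Hochberg method over the 13329 probe sets, and a probe set was called at an adjusted p under 0.05. Every adjusted p below comes from this limma model unless another test is named. All tests were two-sided.

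The pairing comes from the labels and was checked in the values. Deviations of the members of a pair from their group means correlated at 0.21 to 0.51 across probe sets, against a median of -0.10 between samples of different pairs, and all 7 samples at 32 °C correlated best with their own partner. The labels do not say how far cultures of different sessions were independent beyond their separate sessions.

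The genes named in the text follow a rule fixed, like the tests, the gene lists and the alternatives, before the data were examined. It takes CIRBP and RBM3, the 12 genes with the largest rise and the 12 with the largest fall, and up to 4 members of each gene list with the smallest adjusted p. The largest changes were taken among genes whose representing probe set was called, changed by at least 1 on the log2 scale and went the same way in all 7 pairs. A gene is represented by the probe set with the highest mean among those that name it alone. The 28 lists whose members the text describes most closely were picked after the list results were seen. Where a count of called members of these was 5 or fewer, members outside the rule were named as well, whether or not their calls held under the alternatives, and the text says that their values had been seen.

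A total of 59 gene lists were fixed, of which 56 had at least 5 tested genes and were tested with camera at a preset correlation of 0.01, adjusted over those 56. Camera with an estimated correlation and fry were run beside it. Lists share genes, so their results are not independent. Exact sign-flip permutation tests over the 7 pair differences, with a smallest p of 0.015625, were used for CIRBP and RBM3 and for measures of array quality. A temperature by period interaction was tested with an F test of 2 coefficients in the same kind of model.

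The alternatives were a fit without the pair, other pseudocounts (the 5th and 40th percentile) or a floor in their place, quantile normalization, centring on array medians, no filter or a filter at the 60th percentile, eBayes without the trend or with robust estimation, each pair left out, each period alone, probe sets with names ending in _x_at or _s_at left out, and other rules for representing a gene.

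The steps were tested on simulated data. In 7 simulated pairs with 13329 probe sets, the model recovered 53.0% of planted changes of 0.5 on the log2 scale, 89.6% of changes of 1 and 95.5% of changes of 1.5, with 6.47% false calls among the calls. With no change planted it called 0 probe sets. The changes of 0.5, 1 and 1.5 were planted in 66, 67 and 67 probe sets, with noise drawn independently for each probe set. In the real data 23.4% of the probe sets were called, so recovery there may differ from these rates. Planted changes of 2 in period C alone were recovered as interactions in 75.5% of cases.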

Results

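The 14 arrays compare THP-1 cells kept for 24 hours at 32 °C (7 cultures), a moderate cooling, with cells kept at 37 °C (7 cultures). The question is which transcripts differ between the temperatures. Median intensity per array lay between 34.9 and 40.5, and log2 intensities of any pair of arrays correlated at 0.89 to 0.98 across probe sets, which are not independent replicates.

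CIRBP and RBM3, which code for RNA-binding proteins known to be induced by mild cold, were examined first in every sample. CIRBP rose in all 7 pairs. The probe set that represents it gave 557 ± 79.0 at 32 °C and 206 ± 39.0 at 37 °C (SD, n = 7), a log2 difference of 1.41 (SE 0.095, adjusted p = 8.88e-07). Its other probe set gave 542 ± 45.3 and 150 ± 41.3, a 3.59-fold difference. RBM3 rose in all 7 pairs as well by its representing probe set, from 272 ± 93.9 to 539 ± 59.4, a log2 difference of 1.05 (SE 0.14, adjusted p = 0.00012). For these 3 probe sets the lowest sample at 32 °C lay above the highest at 37 °C, and the exact sign-flip permutation test gave p = 0.015625, the smallest that 7 pairs allow. A second, dim RBM3 probe set was not called by limma, with 30.4 ± 7.11 at 32 °C and 46.4 ± 10.3 at 37 °C (log2 difference -0.51, adjusted p = 0.057, lower in 6 of 7 pairs). For this probe set the exact sign-flip permutation test gave p = 0.046875, in the opposite direction to the representing one. Of 7 tested genes in the list of cold-inducible RNA-binding proteins, 3 rose (CIRBP, RBM3 and SRSF5) and 1, CARHSP1, fell (-0.50, adjusted p = 0.0069), also adjusted over the list alone. SRSF5 and CARHSP1 were not called without the pair as a block (adjusted p-values of 0.098 and 0.079), and the list did not pass with camera (adjusted p = 0.45).

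**Figure D1:**
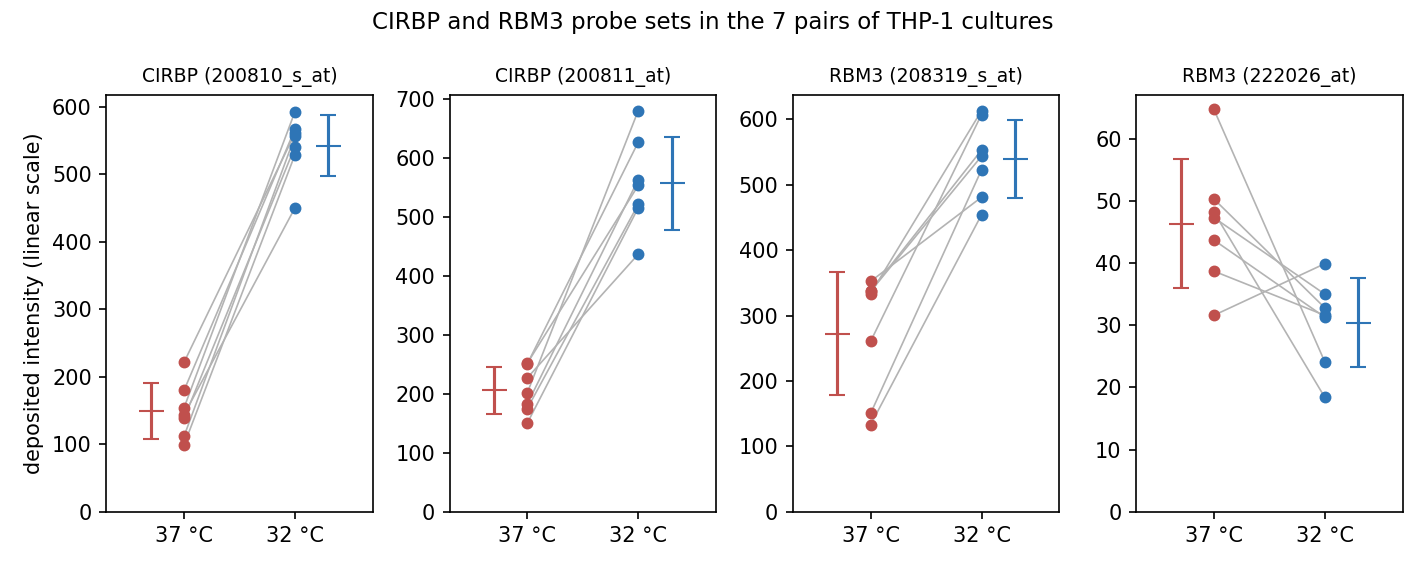
Deposited intensity (linear scale, from 0) of the CIRBP and RBM3 probe sets at 37 °C and 32 °C. Points are single cultures, grey lines join the members of a pair, and the bars beside the points are mean ± SD (n = 7). Samples at 32 °C lie between 436.6 and 679.9 for the representing CIRBP probe set (second panel), above all samples at 37 °C, which reach 251.9.

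Among representing probe sets that went the same way in all 7 pairs, the largest fall belonged to SERPINH1, which codes for the collagen chaperone HSP47, at 25.7 ± 16.4 at 32 °C against 135 ± 53.2 at 37 °C (log2 difference -2.17, SE 0.16, adjusted p = 1.3e-06). HSPH1, a member of the HSP110 chaperones, fell from 525 ± 68.7 to 152 ± 32.3, a 3.38-fold difference. Its other probe set fell 3.20-fold. HSPB1, the small heat shock protein HSP27, fell from 1710 ± 199 to 726 ± 136. The heat shock genes HSPA4L (log2 difference -1.32) and CHORDC1 (-1.36), the cholesterol synthesis gene MSMO1 (-1.26) and BCL11A, a transcription factor of haematopoietic cells (-1.39), also fell at least 2-fold. The other genes of this group were DENND2D (-1.93), NAV3 (-1.49), DDX23 (-1.46), STT3A, a subunit of the oligosaccharyltransferase (-1.37), and REXO2 (-1.23).

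By the same limit the largest rise was that of NDRG2, with 166 ± 31.9 at 32 °C against 47.8 ± 39.8 at 37 °C (log2 difference 1.83, SE 0.22, adjusted p = 5.32e-05). One culture at 37 °C, replicate 7, had an NDRG2 intensity of 137.5 where the others lay between 27.5 and 39, and a second NDRG2 probe set did not pass (log2 difference 0.34, adjusted p = 0.20). CTNNBIP1, an inhibitor of beta-catenin (1.67), SLC15A3, a lysosomal peptide transporter (1.55), the carbonyl reductase CBR3 (2.83-fold) and LSP1, a leukocyte actin-binding protein (1.39), followed. CBR3 was dim, at 13.4 ± 9.48 at 37 °C and 47.3 ± 9.33 at 32 °C, so its fold depends on the pseudocount. RENBP (1.36), COX11 (1.32), the potassium channel KCNQ1 (1.19), CLEC7A, the beta-glucan receptor dectin-1 (1.18), RAB11FIP1 (1.17) and ACP3 (1.17) completed the 12 largest rises within this limit. CIRBP (1.41), described above, is among the 12. CLEC7A was dim too, at 14.8 ± 7.96 at 37 °C and 49.0 ± 44.6 at 32 °C, and so was CTNNBIP1 at 37 °C (21.4 ± 14.1). Their folds depend on the pseudocount as well. Replicate 4 at 32 °C had a CLEC7A intensity of 147.6, where the others reached 49.4. Some probe sets that do not represent their gene rose more. The second COX11 probe set pointed the other way without passing (log2 difference -0.50, adjusted p = 0.078). The 25 genes that the naming rule takes as CIRBP, RBM3 and the largest changes went the same way in all 7 pairs and had adjusted p-values of at most 0.00502.

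In total 3117 of the 13329 tested probe sets were called (23.4%), 1543 higher and 1574 lower at 32 °C. Of these, 51 were higher and 77 lower by 2-fold or more, and 120 of them had the same direction in all 7 pairs. The 2-fold count depends on the pseudocount, with 18 higher and 29 lower at the 40th percentile and 91 higher and 130 lower with a floor in its place. Counted as genes, 1952 of the 8150 represented genes were called, 978 higher and 974 lower, with 27 higher and 39 lower by 2-fold or more. Most changes were small, with a median absolute log2 difference of 0.44 among called probe sets. The balance between directions rests on the scaling: centring each array on its median gave 1800 higher and 1204 lower, so the share of higher calls went from 49.5% to 59.9%, and of the 2-fold calls from 39.8% to 52.8%. Without the pair as a block 1549 probe sets were called, all of them among the 3117.

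**Figure D2:**
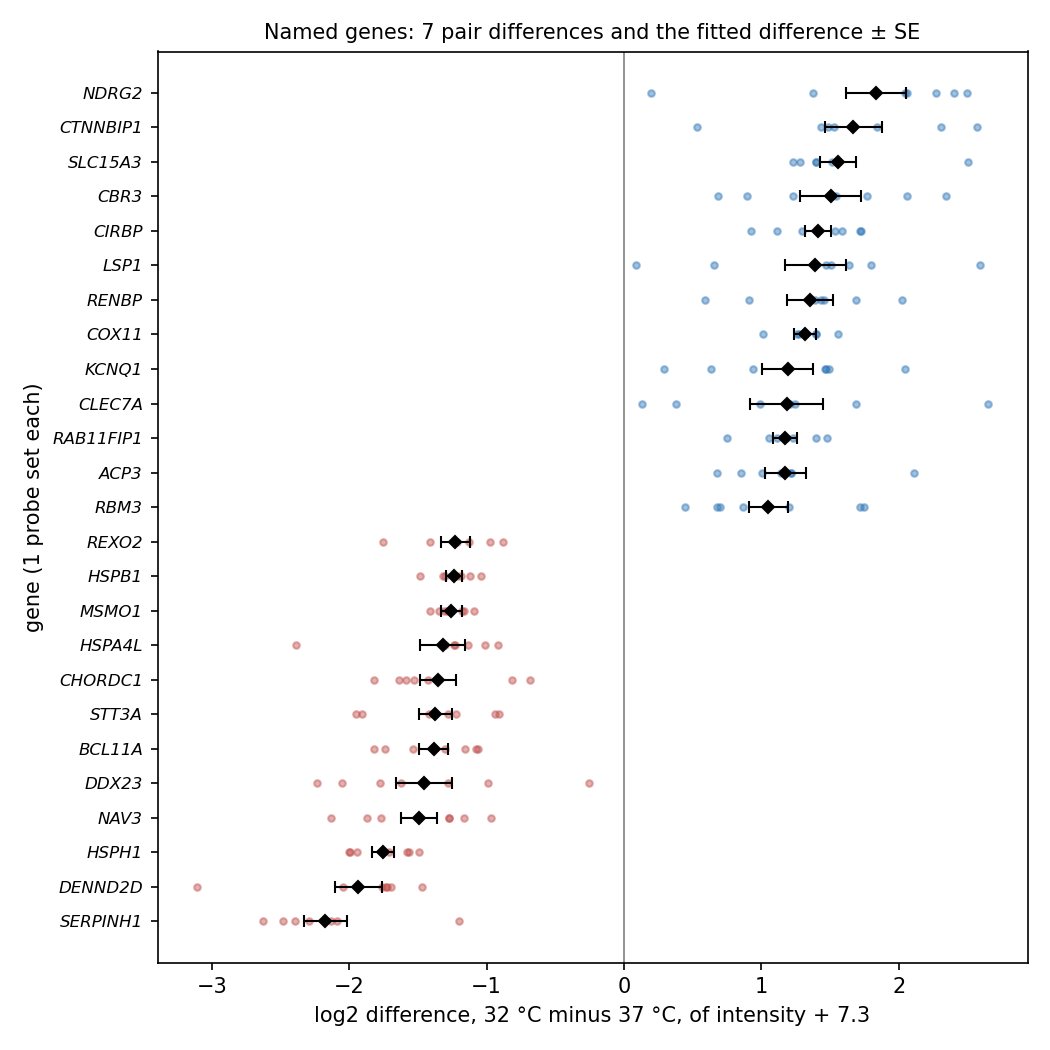
Log2 differences of intensity + 7.3, 32 °C minus 37 °C, of the 25 named genes, 1 probe set each. Small points are the 7 pairs, and black diamonds with bars are the fitted difference ± SE. All points of a gene lie on the same side of 0, from SERPINH1 at -2.17 to NDRG2 at 1.83.

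Of the 56 gene lists tested with camera, 13 passed, 5 higher and 8 lower at 32 °C. With an estimated correlation 0 passed, with 4 at an unadjusted p under 0.05, and fry called 27 lists, 11 of the 13 among them. Counts of members are given for each list below. They use no estimate of the correlation, but members that move together are not independent evidence. The estimated correlation was 0.33 for mitosis and 0.35 for the ATF4 list, for example. For comparison, 978 of all 8150 represented genes were called higher and 974 lower. With genes represented by probe sets other than _x_at and _s_at, the ATF4, MYC, tRNA synthetase, immediate early, monocyte and ribosomal lists described below no longer passed (adjusted p-values of 0.15 to 0.44).

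Several chaperone genes fell at 32 °C, and a few rose. Of 12 tested small heat shock genes and targets of the heat shock factor HSF1, 5 fell and 0 rose, namely HSPB1, SERPINH1, CHORDC1, FKBP4 (log2 difference -1.13, SE 0.14, adjusted p = 6.82e-05) and STIP1 (-0.49), the last named after its value was seen. The list was lower with camera (adjusted p = 0.00235), a call lost with an estimated correlation (adjusted p = 0.46 with an estimated correlation). Adjusted over the list alone, 6 fell and 1 rose. Of 17 members of the HSP70 and HSP90 families and the mitochondrial chaperonins, 6 fell and 3 rose, also when adjusted over the list alone. HSPE1 fell from 581 ± 109 to 278 ± 68.5, HSPD1 from 2775 ± 127 to 1550 ± 347 and HSP90AA1, the inducible cytosolic HSP90, from 3072 ± 269 to 1848 ± 204. The 3 that rose were HSPA5, the chaperone of the endoplasmic reticulum (0.27, adjusted p = 0.011), and, named after their values were seen, HSPA14 (0.41, adjusted p = 0.013) and HSPA4 (0.19, adjusted p = 0.047), with adjusted p-values of 0.23, 0.10 and 0.43 without the pair as a block. The HSPA4 call also ended without replicate 1, 2, 3, 4, 6 or 7 (adjusted p-values of 0.061 to 0.12). The list passed with camera (adjusted p = 0.023) and not with an estimated correlation (adjusted p = 0.46 with an estimated correlation). It did not pass with genes represented by probe sets other than _x_at and _s_at (adjusted p = 0.64) or without the intensity trend (adjusted p = 0.067).

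The cytosolic chaperonin TRiC with prefoldin had 6 of 12 members lower and 0 higher, also adjusted over the list alone. CCT7 (log2 difference -0.62, SE 0.068), CCT3 (-0.59) and CCT4 (-0.58), subunits of TRiC, were lower in all 7 pairs. Camera gave an adjusted p = 0.012, against an adjusted p = 0.46 with an estimated correlation. Among 20 DNAJ co-chaperones, 5 fell and 1 rose, also adjusted over the list alone. DNAJA1 fell from 911 ± 121 to 405 ± 69.4 and DNAJB1 from 291 ± 66.8 to 162 ± 8.39, while the list as a whole did not pass (adjusted p = 0.18). Named after their values were seen, DNAJC9 was the member that rose (0.29, adjusted p = 0.028) and DNAJA3 the weakest that fell (-0.28, adjusted p = 0.041). Neither was called without the pair as a block (adjusted p-values of 0.20 and 0.066), DNAJC9 was not called without replicate 1, 3, 4 or 5, and DNAJA3 was not called without any 1 of replicates 1 to 6. Of 23 chaperones and unfolded-protein genes of the endoplasmic reticulum, 2 rose, HSPA5 and HERPUD1, and 1, EDEM1, fell (1 and 1 adjusted over the list alone). None of the 3 was called without the pair as a block (adjusted p-values of 0.23, 0.29 and 0.39), HERPUD1 was not called without replicate 1, 2, 3, 4, 5 or 7 either, and the list did not pass (adjusted p = 0.95).

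Genes of cholesterol synthesis that were called fell. Of 17 tested, 9 were lower and 0 higher, and 12 were lower adjusted over the list alone. MSMO1 fell from 233 ± 57.3 to 93.5 ± 23.5, SQLE, the squalene epoxidase, from 940 ± 105 to 459 ± 61.0 and SC5D from 321 ± 15.6 to 233 ± 22.2. INSIG1, a sterol-regulated gene of the same list, fell from 410 ± 76.1 to 236 ± 62.8. The median of the list was -0.27 on the log2 scale, below 0 in all 7 pairs, and camera gave an adjusted p = 9.08e-06, against an adjusted p = 0.46 with an estimated correlation. In the list of fatty acid synthesis and desaturation, 3 of 11 rose and 2 fell (4 and 2 adjusted over the list alone, 1 and 1 without the pair as a block). SREBF1, the gene of a transcription factor of lipid synthesis, rose (0.86, SE 0.18, adjusted p = 0.00344), and ACACA, the acetyl-CoA carboxylase, fell (-0.59, adjusted p = 0.000303), and the list did not pass (adjusted p = 0.47). The desaturase SCD, named after its value was seen, fell (-0.32, adjusted p = 0.033), a call lost without the pair as a block (adjusted p = 0.39) and without replicate 2, 3, 6 or 7 (adjusted p-values of 0.066 to 0.097).

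Most called genes of mitosis rose. Of 45 tested, 19 were higher and 1 lower, and 22 were higher and 2 lower adjusted over the list alone. Only 3 were higher and 0 lower without the pair as a block. The mitotic kinases PLK1 (121 ± 38.9 at 37 °C, 219 ± 80.6 at 32 °C) and AURKA (253 ± 26.1 and 378 ± 75.3) rose. BIRC5, or survivin, rose by its representing probe set (0.89, adjusted p = 1.95e-05), while another of its probe sets was called lower (-0.80, adjusted p = 0.026). CKS2 was the member that fell (-0.50, adjusted p = 0.000198, but 0.079 without the pair as a block). The list median was 0.24 and above 0 in all 7 pairs, and camera gave an adjusted p = 9.08e-06, against an adjusted p = 0.50 with an estimated correlation.

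Of 43 genes of DNA replication, 14 were lower and 1 higher (14 and 2 adjusted over the list alone, 3 and 0 without the pair as a block), and the others were not called. CDC6, which loads the replicative helicase, fell from 98.3 ± 22.1 to 55.9 ± 20.2, and MCM6, a subunit of that helicase, from 742 ± 140 to 510 ± 171. GINS2 fell by 0.90 on the log2 scale (adjusted p = 0.000255, but 0.089 without the pair as a block). RFC3, named after its value was seen, was the member that rose (0.26, adjusted p = 0.016), a call lost without the pair as a block (adjusted p = 0.34) and without replicate 1 (adjusted p = 0.051). The list as a whole did not pass (adjusted p = 0.060). MYC fell from 507 ± 119 to 316 ± 77.1, and 5 of 14 genes of its list, which shares 7 genes with other lists, fell while 0 rose (6 and 0 adjusted over the list alone). The others that fell were FKBP4, CAD (-0.37), CDK4 (-0.24) and, named after its value was seen, the ornithine decarboxylase ODC1 (-0.38, adjusted p = 0.035). Without the pair as a block CAD, CDK4 and ODC1 were not called (adjusted p-values of 0.10, 0.11 and 0.43), and ODC1 was not called without replicate 1, 2, 3 or 4 either. By culture period ODC1 differed by -0.46 in A, -0.90 in B and 0.02 in C (F test of the interaction, adjusted p = 0.51). That list passed with camera (adjusted p = 0.021), and neither with an estimated correlation (adjusted p = 0.46 with an estimated correlation) nor without the pair as a block (adjusted p = 0.059) nor without replicate 2 (adjusted p = 0.051). Of 21 genes of nucleotide synthesis, 7 fell and 1 rose, also adjusted over the list alone (3 and 0 without the pair as a block). IMPDH2, the rate-limiting enzyme of guanine nucleotide synthesis, fell from 990 ± 136 to 556 ± 186 and GART from 165 ± 22.6 to 78.9 ± 22.6, and the list did not pass (adjusted p = 0.067). GMPS, named after its value was seen, was the member that rose (0.26, adjusted p = 0.049), a call lost without the pair as a block (adjusted p = 0.48) and without replicate 1, 3, 4, 6 or 7 (adjusted p-values of 0.085 to 0.13).

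Genes of the amino acid response driven by ATF4 and tRNA synthetase genes that were called were mostly lower. Of 18 genes of the ATF4 list, 10 fell and 2 rose (11 and 4 adjusted over the list alone, 2 and 2 without the pair as a block). VLDLR, a lipoprotein receptor gene, fell from 278 ± 18.5 to 152 ± 26.0. PHGDH and MTHFD2, enzymes of serine and folate metabolism, fell (-0.59 and -0.44), with adjusted p-values of 0.17 and 0.092 without the pair as a block. Replicate 4 at 37 °C stood apart with the highest PHGDH, MTHFD2, TARS1 and IARS1, and without this pair all 4 kept their call. ATF3 (0.80) and the cystine transporter SLC7A11 (0.67, named after its value was seen) were the members that rose. The list barely passed with camera (adjusted p = 0.045) and not with an estimated correlation (adjusted p = 0.65 with an estimated correlation), with fry (adjusted p = 0.054), without the pair as a block (adjusted p = 0.14), with the filter at the 60th percentile (adjusted p = 0.051), without the intensity trend (adjusted p = 0.070) or without replicate 1, 2, 3 or 4 (adjusted p-values of 0.060, 0.068, 0.084 and 0.12). Of 16 tRNA synthetases, 6 fell and 1 rose, also adjusted over the list alone (3 and 0 without the pair as a block). IARS1 (-0.75), TARS1 (-0.54) and EPRS1 (-0.49) fell in all 7 pairs, and WARS1, named after its value was seen, rose (0.33, adjusted p = 0.012, but 0.42 without the pair as a block). The synthetase list passed with camera (adjusted p = 0.026), and neither with an estimated correlation (adjusted p = 0.46 with an estimated correlation) nor without the pair as a block (adjusted p = 0.094) nor without the intensity trend (adjusted p = 0.067) nor without replicate 2 (adjusted p = 0.051).

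Among 35 splicing factors of the SR and hnRNP families, 11 fell and 4 rose, also adjusted over the list alone (7 and 2 without the pair as a block). HNRNPA0 fell from 340 ± 29.4 to 213 ± 26.5, and HNRNPU (-0.60) and HNRNPC (-0.63), whose probe sets can match several transcripts, were lower as well. The 4 members that rose were SRSF5 (0.21, adjusted p = 0.018) and, named after their values were seen, U2AF1 (0.40, adjusted p = 0.000635), SRSF6 (0.26, adjusted p = 0.0055, while its other probe set was called lower, by -0.73, adjusted p = 0.0011) and HNRNPAB (0.20, adjusted p = 0.032). SRSF5 and HNRNPAB were not called without the pair as a block (adjusted p-values of 0.098 and 0.62), nor SRSF5 without replicate 1 or 2 and HNRNPAB without replicate 1, 2, 3, 5, 6 or 7. The list did not pass (adjusted p = 0.052). No member of the 52 tested ribosomal protein genes was called by limma (2 at an unadjusted p under 0.05), although that list was lower with camera (median -0.08, adjusted p = 0.016, and adjusted p = 0.75 with an estimated correlation). The ribosomal list did not pass under quantile normalization (adjusted p = 0.60) or with centring on array medians (adjusted p = 0.087), without the pair as a block (adjusted p = 0.17), without the intensity trend (adjusted p = 0.052), with fry (adjusted p = 0.24) or without replicate 3 or 5 (adjusted p-values of 0.12 and 0.087).

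Most called lysosomal genes rose. Of 34 tested, 15 were higher and 3 lower (16 and 4 adjusted over the list alone, 6 and 0 without the pair as a block). The proteases CTSD (142 ± 49.0 at 37 °C, 232 ± 78.5 at 32 °C), CTSB (430 ± 133 and 790 ± 409) and CTSC (602 ± 46.9 and 812 ± 84.1) rose in all 7 pairs. CTSB stood at 1690.2 in replicate 4 at 32 °C, where the other cultures reached 746.3. The hydrolase genes TPP1 (-0.26), NEU1 (-0.35) and MANBA (-0.29), named after their values were seen, fell, with adjusted p-values of 0.40, 0.22 and 0.41 without the pair as a block, and MANBA was not called without replicate 2 (adjusted p = 0.066). The list median was 0.16, above 0 in all 7 pairs, and camera gave an adjusted p = 0.00448, against an adjusted p = 0.46 with an estimated correlation. Of 31 proteasome genes, 10 rose and 2 fell (13 and 2 adjusted over the list alone, 4 and 1 without the pair as a block). PSMD3 rose (0.42, adjusted p = 0.00224), and PSMC6 fell (-0.44, adjusted p = 0.00154). The proteasome list passed with camera (adjusted p = 0.026), and neither with an estimated correlation (adjusted p = 0.47 with an estimated correlation) nor with quantile normalization (adjusted p = 0.083), nor without the pair as a block (adjusted p = 0.078), nor with the filter at the 60th percentile (adjusted p = 0.071), nor without the intensity trend (adjusted p = 0.053), nor without replicate 1 or 4 (adjusted p-values of 0.060 and 0.059).

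Immediate early genes, which respond within minutes to many stimuli, were higher where called. Of 19 tested, 6 rose and 0 fell (7 and 0 adjusted over the list alone). FOS rose from 45.8 ± 16.9 to 85.9 ± 16.8, IER2 from 319 ± 90.4 to 531 ± 48.2 and JUND from 635 ± 158 to 997 ± 301, each in all 7 pairs. The list passed with camera (adjusted p = 0.027) and not with an estimated correlation (adjusted p = 0.46 with an estimated correlation), without the pair as a block (adjusted p = 0.058) or without replicate 2 or 3 (adjusted p-values of 0.051 and 0.060).

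**Figure D3:**
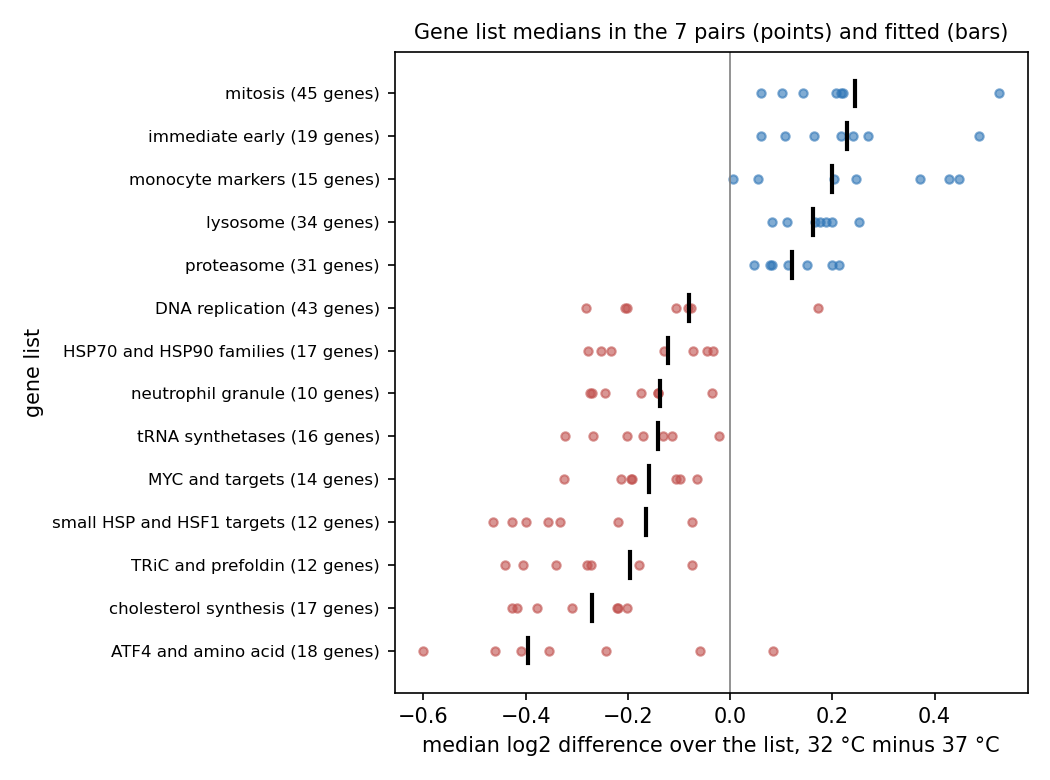
Median log2 difference, 32 °C minus 37 °C, over the tested genes of 14 gene lists. Points are the 7 pairs, and black bars are the median of the fitted differences. Cholesterol synthesis (-0.27) lies below 0 and mitosis (0.24) above 0 in all 7 pairs, while DNA replication (-0.08) lies above 0 in 1 pair.

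Markers of the myeloid lineage moved in different directions. Of 15 monocyte markers, 7 rose and 1 fell (8 and 1 adjusted over the list alone, 2 and 1 without the pair as a block). S100A9 and S100A8, the subunits of calprotectin, rose in all 7 pairs, from 676 ± 294 to 1399 ± 482 and from 1424 ± 715 to 2656 ± 957. MNDA fell (-0.61, adjusted p = 0.000459). Both cultures of replicate 4 had low S100A8, 513.8 at 32 °C and 227.1 at 37 °C, and the unblocked fit called neither S100A9 (adjusted p = 0.066) nor S100A8 (adjusted p = 0.20). The list passed with camera (adjusted p = 0.015), and neither with an estimated correlation (adjusted p = 0.46 with an estimated correlation) nor without the pair as a block (adjusted p = 0.11) nor with the filter at the 60th percentile (adjusted p = 0.11), where its median went from 0.20 to 0.09. Of 10 neutrophil granule genes, 4 fell and 0 rose, also adjusted over the list alone. Of these only MS4A3 was called without the pair as a block, where PRTN3 and RNASE2 were not (adjusted p-values of 0.49 and 0.29). Replicate 4 had the lowest MS4A3 and PRTN3 at both temperatures. MS4A3, a marker of granulocyte and monocyte progenitors, fell from 700 ± 236 to 358 ± 127, and CTSG, cathepsin G, by 0.65 on the log2 scale (adjusted p = 0.000349, but 0.088 without the pair as a block), while the list did not pass (adjusted p = 0.060). Of 11 macrophage differentiation markers, 2 rose and 2 fell (4 and 3 adjusted over the list alone). GPNMB, which rose, and SPP1, which fell, were not called without the pair as a block (adjusted p-values of 0.39 and 0.54), nor SPP1 without replicate 2 (adjusted p = 0.051). TREM2 fell from 379 ± 33.7 to 212 ± 24.9, CTSK rose (0.49, adjusted p = 0.000915), and the list did not pass (adjusted p = 0.53).

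Few markers of cells that the line should not hold were called. Of the lists fixed for T cells (7 tested), B cells (4), erythroid cells (4), megakaryocytes and platelets (7), fibroblasts (7) and dendritic cells (6), 0 of 35 genes were called by limma, also adjusted over the list alone, and 3 had an unadjusted p under 0.05. Of 5 natural killer cell markers 1, KLRD1, named after its value was seen, fell (-0.58, adjusted p = 0.037), a call lost without the pair as a block (adjusted p = 0.25) and without replicate 1, 3, 5 or 6 (adjusted p-values of 0.082, 0.076, 0.083 and 0.072). Of 3 epithelial markers 1, MUC1, named in the same way, rose (0.68, adjusted p = 0.00289).

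The cold effect was compared between the 3 culture periods. In period A CIRBP differed by 1.41, in B by 1.66 and in C by 1.25 on the log2 scale, and RBM3 by 1.03, 1.73 and 0.61. Neither interaction passed (adjusted p = 0.90 for CIRBP and 0.27 for RBM3). That adjustment runs over all tested probe sets, so for RBM3, a gene fixed beforehand, it does not show an equal effect in the periods. The RBM3 pair differences were 0.86 and 1.20 in A, 1.72 and 1.75 in B and 0.44 to 0.70 in C, without overlap between periods. Of the tested probe sets only that of FOLR1, described next, had a stronger interaction than RBM3. A single probe set passed the interaction test, that of FOLR1, the folate receptor alpha, named after its values were seen (adjusted p = 0.000472), with log2 differences of 0.37 in A, -1.74 in B and 0.24 in C. Without the intensity trend 0 probe sets passed, so this call ended. At an unadjusted p under 0.05 there were 795 probe sets, where 666 are expected by chance. Over the tested probe sets, which are not independent, the log2 differences correlated at 0.60 between A and B, 0.55 between A and C and 0.50 between B and C. Fitted within a period, 1494 probe sets were called in A, 352 in B and 856 in C.

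Measures of array and RNA quality were compared in the same pairs with exact sign-flip permutation tests. The 3' to 5' difference of the GAPDH control probe sets was 0.17 ± 0.13 at 32 °C and 0.18 ± 0.20 at 37 °C on the log2 scale (exact p = 0.95), and that of beta-actin was 0.27 ± 0.12 and 0.28 ± 0.14 (exact p = 0.94). Array medians were 37.0 ± 1.65 and 38.5 ± 1.82 (exact p = 0.17). None of the 5 planned measures passed, with Benjamini-Hochberg adjusted p-values of at least 0.59. Of the control measures added after the data were seen, the poly-A control probe sets were lower at 32 °C in 6 of 7 pairs, with mean log2 intensities of 1.66 ± 0.31 against 1.96 ± 0.44 (exact permutation p = 0.046875, not adjusted). On the linear scale these means lie below 7.3, the 20th percentile of the table, while the hybridization spikes had mean log2 intensities of 8.12 and 8.20. The poly-A controls were thus near background, and no conclusion is drawn from their difference.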

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

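The contrast of mitotic with replication genes, the test of opposite calls at an adjusted p of 0.001 and the splits counted for single gene lists were chosen after the results were seen.

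Chance was examined by regrouping the samples. Of the 64 splits that part all 7 pairs, only the real one, 1 of 64, called as many as 3117 probe sets, and the highest of the others called 2. This argues against chance for that count, at the smallest share that 64 splits can give. The same holds for the probe sets changed at least 2-fold, 51 higher and 77 lower, whose total was reached by 1 of 64 splits, with 2 as the highest of the others. In the other splits some pairs are swapped, so real differences add to the residual spread and lower the calls. The distance between 3117 and 2 is therefore no measure of how unlikely chance is. Of 100 drawn splits of the 14 samples into 7 and 7 that need not part the pairs, 1 reached 3117, and the highest of the others called 1492. For the 13 gene lists chance cannot be excluded, since 6 of 64 splits gave as many and the highest of the others gave 20. The other splits that gave as many swapped only 1 or 2 of the 7 pairs, so they keep most of the real contrast. With 3 pairs swapped the highest was 11 lists. Counted for single lists, cholesterol synthesis had a camera p as small in 1 of the 64 splits, small heat shock genes in 2, TRiC and lysosome in 4 each, mitosis in 14, DNA replication in 23 and ribosomal proteins in 35. For the other called lists the count was 3 for the HSP70 and HSP90 families, 4 for tRNA synthetases, 5 for immediate early genes, 6 for monocyte markers, 8 for MYC, 12 for the proteasome and 20 for ATF4.

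Among 350 groups of 7 values checked, a single sample stood far from the others in 28, where chance gives about 17.5. In 20 of the 26 such groups of gene values that sample was replicate 4. At both temperatures replicate 4 was lowest for S100A8 (ratio of the gap to the range 0.92 at 32 °C and 0.58 at 37 °C), S100A9 (0.82 and 0.68), PRTN3 (0.58 and 0.76) and MS4A3 (0.62 and 0.60). At 32 °C it was also highest for CTSB (ratio 0.68), CEBPB (0.68), NEU1 (0.66), CLEC7A (0.59) and AARS1 (0.57), and lowest for MT1E (0.79) and NAV3 (0.69). At 37 °C it was highest for TARS1 (ratio 0.69), HERPUD1 (0.65), IARS1 (0.65), MTHFD2 (0.62) and PHGDH (0.61). PHGDH stood at 713.2 in that culture, where the others reached 277.3, and S100A8 at 227.1, where the lowest of the others was 917.1. Without replicate 4, 2696 probe sets were called, 126 of them changed at least 2-fold, and 13 gene lists.

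The other samples far from their group were replicate 7 for NDRG2 at 37 °C (ratio 0.80), replicate 3 for SRSF5 at 32 °C (0.72), replicate 5 for ATF3 at 37 °C (0.69), and replicate 6 for INSIG1 (0.61) and HSPA4L (0.58) at 32 °C and BST2 at 37 °C (0.57). Replicate 6 also had the highest beta-actin 3' to 5' difference at 32 °C (ratio 0.65) and the lowest 18S ribosomal RNA control at 37 °C (0.62), at 1.32 on the log2 scale where the lowest of the others was 5.67.

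The cold effect on FOLR1 differed between culture periods (interaction adjusted p = 0.000472). Both pairs of period B had less at 32 °C, with intensities of 378 against 1168.7 and 237 against 884.6, while all pairs of the other periods had more. In 9 of 100 assignments of the pairs to periods of the same sizes at least 1 probe set passed, with 1 as the highest of the others, so chance cannot be excluded for this count of 1, which was 0 without the intensity trend.

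Most called mitotic genes rose while most called replication genes fell, a contrast picked after the list results were seen and with few members called without the pair as a block, and the difference of the 2 list medians within a pair averaged 0.32 ± 0.096 on the log2 scale (SD, n = 7 pairs). The difference was above 0 in 7 of 7 pairs. This largely followed from the choice, since the mitotic median was above 0 in 7 pairs and the replication median in 1. It was at least 0.17 in the 4 pairs whose GAPDH 3' to 5' value was higher at 32 °C and at least 0.30 in the other 3. The sign of the difference thus did not follow this value, but RNA quality in general was not decided by it. A response of the arrays that depends on intensity could not be excluded for the replication genes, whose median lay at percentile 4.01 of 10000 lists matched on intensity, while the mitotic median lay at percentile 100. An effect of temperature stays open as a hypothesis, and the pair medians would also differ if cells were distributed differently over the cell cycle, which was not tested.

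Probe sets of the same gene were called in opposite directions for 50 genes. That number does not exceed the 81.5 false calls allowed among the 1631 called probe sets of genes with several tested probe sets. A false call gives such a gene only where another of its probe sets is called the other way. This limit is therefore too lenient to decide whether false calls account for the 50. The minority probe sets of a gene are those of the direction with fewer calls, or its dimmest called ones where the numbers were equal. Probe sets that can match several transcripts made up 49.1% of the minority probe sets and 72.8% of those of genes called 1 way (Fisher's exact p = 0.000331). This cannot decide whether such probe sets are a source of opposite calls, since they may also stand on the other side of a gene. The minority probe sets were dimmer by a median of -0.68 on the log2 scale (permutation p = 0.00384). Part of this difference is built in, since the dimmest were taken where the numbers were equal. Low signal therefore remains open and was not decided. At an adjusted p under 0.001 there were still 7 such genes, CNPY2, H2AZ2, RER1, SYNCRIP, TIA1, UBAP2L and UBE2J1, where 0.44 false calls are allowed, so for these 7 false calls are argued against. Probe sets that match other transcripts could give such calls too, and several of those involved end in _s_at, among them both of RER1 and both of UBE2J1. Neither this nor the hypothesis of transcript forms that differ with temperature was tested for the 7.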

How the results depend on the processing

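CIRBP and RBM3 kept their direction and their call in all 17 alternatives run on them, with log2 differences of 1.341 to 1.495 and 0.933 to 1.151. The 25 named genes kept theirs wherever their probe sets were tested. In the alternatives run on them no named gene, examined list member or called gene list changed direction. These leave out single periods, where the median of the HSP70 and HSP90 list was above 0 in period C (0.01) and that of the ribosomal list in period A (0.02). Among list members ODC1, for example, was at 0.02 in period C. Still, the balance of higher and lower calls turned with the scaling, to 1596 higher and 1494 lower under quantile normalization and 1800 and 1204 with centring on array medians. With no replicate block 1549 probe sets were called in place of 3117, all 1549 of them shared, and 7 gene lists in place of 13, and 55 of the 142 list members and genes with opposite probe sets examined, many of them picked after the results were seen, lost the call, among them S100A8, S100A9, CTSH, CAD, GPNMB, SPP1, PRTN3, RNASE2, ME1, ACSL1, EDEM1, HERPUD1, CD14, MYD88, RELB, PER2, MT1E and MT1X. All members that lost the call under another setting were among these 55, with GMPS, HNRNPAB, HSPA4, DNAJA3, ODC1, SCD, IFITM3, KLRD1, HERPUD1 and DNAJC9, all at adjusted p-values over 0.028, the least stable. The 2-fold count depends on the pseudocount, by its construction: 51 higher and 77 lower became 47 in all with the 40th percentile and 221 with a floor in place of a pseudocount. It was 79 with the filter at the 60th percentile, where fewer dim probe sets were tested. Without probe sets ending in _x_at or _s_at, 1337 were called and 51 changed at least 2-fold, with fewer tested. With fewer pairs, period A alone gave 1494 calls and 218 at least 2-fold, period B 352 calls and period C 856. Without the intensity trend the period interaction called 0 probe sets and camera 8 gene lists, and the cause was not tested. Gene lists numbered 5 when genes were represented without _x_at and _s_at probe sets, 0 with an estimated correlation and 27 with fry, and the cause of the first was not tested. With each pair left out in turn, the ranges were 2450 to 2884 calls, 124 to 149 at least 2-fold, 9 to 18 gene lists and 25 named genes throughout. Cholesterol synthesis, small heat shock genes, TRiC, lysosome and mitosis, 5 lists, kept their call under every setting but the estimated correlation, though the small heat shock list could not be tested without _x_at and _s_at probe sets. Of the 142, 84 kept their call under all settings, and 3 had no call in the main fit and gained it under 1 setting. Probe sets near background limit what can be seen, since the pseudocount shrinks their changes.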

Other observations

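In the lists of NF-kB, pattern recognition and cytokine genes every called gene was higher at 32 °C. The number of calls in these lists did not stand out, since 24.0% of all represented genes were called. The NF-kB list shares 6 genes with other lists. Of 18 genes of the NF-kB pathway, 4 rose and 0 fell, also adjusted over the list alone. NFKBIA, the inhibitor that NF-kB itself induces, rose from 239 ± 45.9 to 426 ± 148 (SD, n = 7), and TNFAIP2 from 169 ± 66.1 to 310 ± 109. RELB, another that rose, was not called without the pair as a block (adjusted p = 0.22). The list did not pass with camera (adjusted p = 0.078). Of 17 genes of pattern recognition, 4 rose and 0 fell, also adjusted over the list alone, among them the signalling kinase IRAK1, from 503 ± 51.9 to 910 ± 71.9, and this list did not pass either (adjusted p = 0.060). CD14 and MYD88 lost their call without the pair as a block (adjusted p-values of 0.053 and 0.14). Of 17 tested cytokine and chemokine genes, 3 rose and 0 fell, also adjusted over the list alone. TGFB1 (log2 difference 0.58) and CXCL8, the chemokine interleukin-8 (0.93), rose, as did TNF (0.79), which lost its call without the pair as a block (adjusted p = 0.17). Of 28 interferon-responsive genes 3 rose and 3 fell, also adjusted over the list alone, and BST2, or tetherin, fell from 202 ± 33.7 to 95.1 ± 14.1. Named after their values were seen, IFITM3 rose (0.29, adjusted p = 0.037) and XAF1 fell (-0.78, adjusted p = 0.010). Without the pair as a block all 3 rises, of IFITM1, IFI35 and IFITM3, were lost (adjusted p-values of 0.071, 0.076 and 0.40), as were the falls of PSMB9 and XAF1 (adjusted p-values of 0.39 and 0.071), and the rise of IFITM3 also without replicate 3, 4 or 5 (adjusted p-values of 0.070 to 0.11).

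Of 9 tested genes of the circadian clock, 5 rose and 0 fell (5 and 2 adjusted over the list alone, 3 and 0 without the pair as a block). The clock repressor NR1D2 rose from 32.9 ± 12.5 to 61.7 ± 10.8, and the clock output gene DBP from 42.2 ± 14.1 to 66.4 ± 12.5, each in all 7 pairs. BHLHE40, named after its value was seen, rose as well (0.54, adjusted p = 0.013, but 0.15 without the pair as a block). The list did not pass with camera (adjusted p = 0.078). Among 16 regulators of apoptosis, 3 rose and 1 fell, also adjusted over the list alone. BCL2, which blocks apoptosis, fell from 317 ± 53.9 to 171 ± 34.5, while CASP8 (0.77), BAD (0.55) and BID (0.36) rose. That list did not pass (adjusted p = 0.90). Of 9 metallothionein genes 3 fell and 0 rose, also adjusted over the list alone (1 and 0 without the pair as a block). The probe sets of these near-identical genes can match several of them, so their values are uncertain, and the list did not pass (adjusted p = 0.078).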
